A study of Mus musculus with 10 samples.

How the data were processed

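RNA was taken from regulatory T cells of the mouse spleen, sorted as CD4+ cells that carried a red fluorescent reporter at Foxp3. Further gates on CD62L, CD69 and Klrg1 split these cells into subsets. The mice were females of 9 to 14 weeks on the C57BL/6 background. Per the labels, 20 to 50 ng of RNA per sample were amplified and hybridised to Affymetrix Mouse Gene ST 1.0 arrays. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises probes, and its version is not given in the sources used here. The deposited values are RMA log2 intensities per the labels, and their range on the arrays was checked against that unit. Whether all arrays were normalized together is not given in the sources used here.

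The table held 35556 probe sets. Of these, 21789 had 1 gene symbol in the probe table, 1621 had several and 12146 were not in it. Where a gene had several probe sets, the one with the highest mean over the grouped arrays was taken, which left 19938 genes. No intensity filter was applied.

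Arrays were grouped by the markers in their labels. FR1 (CD62Lhi CD69- Klrg1-) had 2 arrays, FR2 (CD62Llo CD69- Klrg1-) had 2, FR3 Klrg1- (CD62Llo CD69+ Klrg1-) had 4 and FR3 Klrg1+ (CD62Llo CD69+ Klrg1+) had 1. Another array was titled as FR3 while its marker text was that of FR1, so it was placed in no group and left out of every comparison. Arrays with the same label are described as biological replicates. The number of arrays limits the precision of every value.

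The 5 comparisons between groups were made with limma 3.58.1 in R 4.3.3, with 1 fit over the 9 grouped arrays, moderated variances and Benjamini-Hochberg adjustment over the 19938 genes at a threshold of 0.05. A group of 1 array was assumed to vary like the others. Lists of genes were tested with camera of limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists and 5 comparisons together. The lists covered the sort markers, naive and lymphoid homing genes, Treg identity, effector Treg genes, co-inhibitory receptors, chemokine receptors and integrins, IL-2 and STAT5 targets, TCR-induced immediate genes, cell cycle, apoptosis, NK receptors and cytotoxicity, T helper regulators and cytokines, type I interferon response, TGF-beta pathway, glycolysis, cholesterol synthesis, oxidative phosphorylation, heat shock and stress, cytosolic ribosomal proteins, and markers of B cells, plasma cells, macrophages and monocytes, dendritic cells, neutrophils, erythroid cells, platelets, NK cells, CD8 T cells and T cells. The step from FR1 to FR2 and the step from FR3 Klrg1- to FR3 Klrg1+ were set side by side by a correlation across genes and by the overlap of calls.

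Genes were named by a rule: in each comparison the 10 higher and the 10 lower genes with the largest change among those past the threshold whose arrays did not overlap between the groups, the sort markers, and up to 4 members of each list that passed. Immunoglobulin and T cell receptor segments, predicted genes, olfactory and vomeronasal genes and small RNA genes were left out of the first part. The groups, tests, lists, this rule and a set of alternatives were chosen before the data were examined. These alternatives were an intensity trend in the variance, leaving out genes under the percentile 40 of the mean, quantile normalization, every probe set, every row of the table, only the arrays of the groups compared, array weights, the replicate number as a block, an absolute log2 fold change of at least 1, an estimated correlation in camera, the rotation test fry, and leaving out each array of a replicated group in turn.

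The arrays fell into 2 sets by their correlation, described at the start of the report. The array set as a block in the fit, fits within each set, and the naming rule applied to the fit with the block were added after the data were seen. In the fit with the block, differences between groups that share a set come from that set. FR3 Klrg1- is the only group with arrays in both sets, so the block gives the same fold changes as the first set alone for FR1, FR2 and FR3 Klrg1-, and the same as the second set alone for FR3 Klrg1+ against FR3 Klrg1-.

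The fit was tested on simulated data with the same groups and sets. At once 100 genes were moved by 1 and another 100 by 2 on the log2 scale, some up and some down. The data were drawn from the fit with the block, with the same set difference in every group. Better recovery with the block was therefore built in, and a set difference that varies between groups was not simulated. For FR2 against FR1 it found 29% and 85% of them without the block and 100% with it. For FR3 Klrg1- against FR1 it found 50% and 91% without the block, and 100% with it. For FR3 Klrg1+ against FR3 Klrg1- it found 15% and 77% without the block, and 93% and 100% with it. For FR3 Klrg1+ against FR1 it found 12% and 72% without the block, and 55% and 100% with it. Calls on genes that had not been moved numbered 0 without the block and 7 to 13 with it. Camera, tested for FR2 against FR1 only, found 10 of 10 shifted lists and 0 others. Genes were drawn independently of each other, so correlation between the genes of a list was not simulated. False list calls from such correlation could not appear.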

Results

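Gene expression was measured on 10 arrays of regulatory T cells sorted from the mouse spleen. Regulatory T cells (Tregs) carry the transcription factor Foxp3. They were divided by CD62L, a homing receptor of lymph nodes, by the activation marker CD69, and by Klrg1, a receptor of differentiated lymphocytes. The groups were FR1 (CD62Lhi CD69- Klrg1-, n = 2), FR2 (CD62Llo CD69- Klrg1-, n = 2), FR3 Klrg1- (CD62Llo CD69+ Klrg1-, n = 4) and FR3 Klrg1+ (CD62Llo CD69+ Klrg1+, n = 1). Array medians lay between 6.15 and 6.31 (RMA, log2). Values below are log2 fold changes with their SE, and a log2 of 1 is a doubling.

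The arrays formed 2 sets that did not follow the groups. The first held FR1, FR2 and FR3 Klrg1- replicates 1 and 2. The second held FR3 Klrg1- replicates 3 and 4, the FR3 Klrg1+ array and the array placed in no group. Arrays of different groups in the same set correlated at 0.972 to 0.987, and FR3 Klrg1- arrays of different sets at 0.918 to 0.921. Gene values and list tests below are therefore also given with the array set as a block, where a fold change equals that within the set that holds both groups. Tested by limma between the sets within FR3 Klrg1-, 3565 genes were higher and 3407 lower in the first set.

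Of the transcripts Klrg1 and Cd69, Klrg1 alone followed its gate. Klrg1 stood at 5.61 ± 0.24 in FR1 (SD, n = 2), 6.51 ± 0.10 in FR2 (SD, n = 2), 7.12 ± 0.40 in FR3 Klrg1- (SD, n = 4) and 12.33 in FR3 Klrg1+. In the first set Cd69 stood at 12.26 ± 0.22 in FR1, 12.02 ± 0.22 in FR2 and 12.09 ± 0.09 in FR3 Klrg1- (SD, n = 2 each), while in the second it was at 9.98 ± 0.36 in FR3 Klrg1- (SD, n = 2) and 9.86 in FR3 Klrg1+. Foxp3 lay between 10.67 and 10.81 in the groups of the first set, and at 9.79 and 9.64 in FR3 Klrg1- and FR3 Klrg1+ of the second. Cd4 lay between 11.13 and 11.63 in the first set and at 9.95 and 10.10 in the second.

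**Figure D1:**
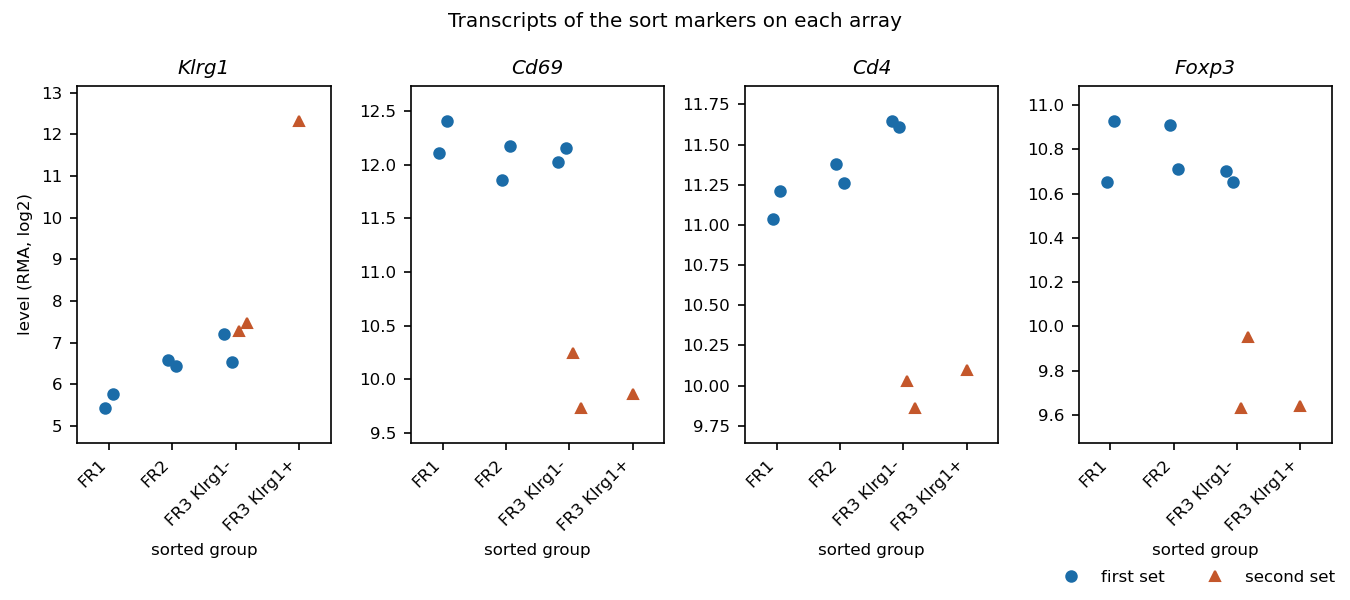
Level of 4 sort marker transcripts (RMA, log2) on each of the 9 grouped arrays, with 1 point per array, circles for the first array set and triangles for the second. Klrg1 is at 12.33 on the FR3 Klrg1+ array, and Cd69, Cd4 and Foxp3 are lower on the second set.

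The comparison of FR2 with FR1 asks what differs between CD62Llo and CD62Lhi Tregs that lack CD69 and Klrg1. FR2 cells had more transcript of the chemokine receptor Ccr2, which rose by 2.58 ± 0.27 (n = 2 and 2), of Itgae, the integrin chain CD103 (2.35 ± 0.26), and of Tigit, a co-inhibitory receptor (2.07 ± 0.20). Fgl2, a secreted suppressor molecule of Tregs, rose by 2.16 ± 0.29, the cytotoxic protease Gzmb by 1.56 ± 0.20, and the chemokine Ccl5 by 1.80 ± 0.15. Of the naive and lymphoid homing genes, Igfbp4 fell by 1.49 ± 0.20 and Atp1b1 fell by 1.48 ± 0.21. The survival gene Bcl2 fell by 1.23 ± 0.17. In all, 41 genes were higher and 11 lower (limma, Benjamini-Hochberg), and 391 and 459 with the array set as a block. All 52 genes were also called with the block, and the first set alone gave 1331.

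Other genes that rose in FR2 were Lilr4b (2.39 ± 0.34), the myosin Myo1f (2.38 ± 0.17), Zdhhc2 (2.11 ± 0.20), Ttc39c (2.11 ± 0.25), the oxidase subunit Cybb (1.89 ± 0.21), the IL-18 receptor chain Il18rap (1.72 ± 0.22), Glrx (1.56 ± 0.15), the TGF-beta activating integrin chain Itgb8 (1.22 ± 0.17) and the transcription factor Tbx21 (1.09 ± 0.16). Cnn3 (-1.71 ± 0.22), Itih5 (-1.52 ± 0.18), Ctsw (-1.49 ± 0.18), Gata1 (-1.40 ± 0.15), Slc35d1 (-1.40 ± 0.18), Dapk1 (-1.06 ± 0.13) and Igsf23 (-0.90 ± 0.13) fell. The adjusted p of these genes ran from 0.017 to 0.0499 without the block (limma, Benjamini-Hochberg). Their fold changes were the same with it, since both groups lie in the first set. Lilr4b in FR1 (4.82) lay below percentile 25 of the arrays, so its fold is a lower bound at best.

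Other genes passed in limma with the array set as a block and not without it, at the same fold change. The chemokine receptors Cxcr3 (2.59 ± 0.14 with the block, adjusted p = 2.29e-07 with it and 0.126 without) and Ccr4 (2.26 ± 0.15, 1.26e-06 and 0.114) rose, as did the cytokine Il10 (2.10 ± 0.21, 2.12e-05 and 0.305), S100a4 (2.36 ± 0.15, 6.05e-07 and 0.885), Pdcd1, the receptor PD-1 (1.01 ± 0.13, 0.000291 and 0.992), and Klrg1 (0.90 ± 0.19, 0.014 and 0.645). The lymphoid homing receptor Ccr7 fell by 1.61 ± 0.13 (4.06e-06 and 0.488), and Gpr83 fell by 1.52 ± 0.18 (0.000115 and 0.292). The values of Cd69 (-0.24 ± 0.18), Cd4 (0.19 ± 0.13) and Foxp3 (0.02 ± 0.15) did not pass with the block.

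Of the 32 measured effector Treg genes, 4 rose over all genes and 17 rose adjusted over the list alone, and 21 and 27 with the block. The list was higher as a group (median 0.91, camera adjusted p = 1.82e-24, adjusted p = 0.179 with an estimated correlation). With the block camera gave 1.07e-38. Of the 20 naive and lymphoid homing genes, 3 fell over all genes and 7 fell adjusted over the list alone, and 12 and 14 with the block. That list was lower as a group (median -0.64, camera adjusted p = 7.07e-14, adjusted p = 0.179 with an estimated correlation). Camera gave 2.34e-17 with the block. Of 28 chemokine receptors and integrins, 2 rose over all genes, and 9 rose and 1 fell adjusted over the list alone (median 0.34, camera adjusted p = 4.36e-06, adjusted p = 0.2 with an estimated correlation, and 5.14e-08 with the block, where 12 rose and 1 fell). Of 13 co-inhibitory receptors, 1 rose on either count, and 4 with the block (median 0.35, camera adjusted p = 0.000969, adjusted p = 0.179 with an estimated correlation). The block took this to 0.000246.

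Of 30 T helper regulators and cytokines, 2 rose, and 6 adjusted over the list alone (median 0.12, camera adjusted p = 0.000702, adjusted p = 0.2 with an estimated correlation). With the block 8 rose and 2 fell, and 11 and 2 over the list alone (0.00131). Of 21 Treg identity genes, 1 rose, and 5 rose and 1 fell adjusted over the list alone (median 0.27, camera adjusted p = 0.0326, adjusted p = 0.803 with an estimated correlation). With the block 7 rose and 2 fell, and 10 and 2 adjusted over the list alone (0.0121). Of 26 genes of NK receptors and cytotoxicity, 4 rose and 1 fell, and 4 and 2 adjusted over the list alone (median 0.06, camera adjusted p = 0.0371, adjusted p = 0.267 with an estimated correlation). With the block 5 rose and 2 fell, and 6 and 2 over the list alone (0.0435).

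Genes of ribosomes and of mitochondrial respiration were lower as groups in FR2. Of 36 oxidative phosphorylation genes 0 passed in limma without the block, over all genes or adjusted over the list alone, while with the block 5 fell over all genes and 18 over the list alone (median -0.36, camera adjusted p = 4.87e-08, adjusted p = 0.2 with an estimated correlation). The block took this to 4.49e-12. Of 32 cytosolic ribosomal protein genes 0 passed in limma on either count, and 5 and 16 fell with the block (median -0.29, camera adjusted p = 2.94e-11, adjusted p = 0.179 with an estimated correlation). This was 7.58e-11 with the block. The 20 cholesterol synthesis genes were lower as a group (median -0.15, camera adjusted p = 0.00746, adjusted p = 0.512 with an estimated correlation, and 0.00983 with the block), with 0 called in limma in any of these counts. The 27 genes of the type I interferon response were also lower (median -0.11, camera adjusted p = 0.00518, adjusted p = 0.2 with an estimated correlation, and 0.0105 with the block). Without the block 2 fell adjusted over the list alone, and with it 3 fell over all genes, and 2 rose and 8 fell over the list alone.

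Glycolysis was lower with the block alone (median -0.16, camera adjusted p = 0.141 without and 0.0462 with it, adjusted p = 0.616 with an estimated correlation and the block). Lists that passed in camera neither without nor with the block are given by median and adjusted p without it: cell cycle (0.10, 0.0903), IL-2 and STAT5 targets (-0.18, 0.109), TGF-beta pathway (0.13, 0.158), heat shock and stress (-0.08, 0.438), the sort markers (0.10, 0.5), apoptosis (-0.02, 0.663) and TCR-induced immediate genes (0.07, 0.847). The markers of B cells (-0.08, 0.429), plasma cells (0.20, 0.694), macrophages and monocytes (0.03, 0.767), dendritic cells (0.09, 0.983), neutrophils (0.04, 0.706), erythroid cells (0.03, 0.978), platelets (0.09, 0.706), NK cells (-0.05, 0.255), CD8 T cells (0.24, 0.255) and T cells (-0.04, 0.694) did not pass either. With the block these medians were the same, and the lowest camera adjusted p was 0.0513, for IL-2 and STAT5 targets. Median, mean and test differed in sign for the TCR-induced immediate genes (mean 0.01, test lower, and higher with the block), the erythroid markers (mean -0.03, test higher), the T cell markers (mean 0.02, test lower) and the dendritic cell markers (test lower). On every array the T cell markers averaged between 10.5 and 11.1, and the mean of every other cell type list was lower.

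The count of 52 rests on each array of both groups: without FR1 replicate 1 or 2, or FR2 replicate 1 or 2, limma called 0 genes (826, 562, 512 and 787 at an unadjusted p under 0.05). Without FR3 Klrg1- replicate 1, 2 or 4 it called 25, 30 and 26. With the block it called 351 and 355 without FR1 replicates 1 and 2 in turn, 253 and 522 without FR2 replicates 1 and 2, and 1331 without FR3 Klrg1- replicate 3 or 4.

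The comparison of FR3 Klrg1- with FR1 spans the gates for both CD62L and CD69. The opioid precursor gene Penk rose by 4.18 ± 0.14 (n = 4 and 2; 4.11 with the array set as a block), and the decoy receptor Il1r2 by 4.09 ± 0.25 (3.82). The suppressive cytokine Il10 rose by 3.18 ± 0.41 (3.74), Tigit by 3.23 ± 0.17 (3.25) and Itgb8 by 2.75 ± 0.15 (2.90). S1pr1, the receptor for exit from lymphoid organs, fell by 2.38 ± 0.10 (-2.37 with the block), and its activator Klf2 fell by 2.76 ± 0.53 (-1.94). The chromatin organiser Satb1 (-2.54 ± 0.21, -2.24) and Igfbp4 (-2.84 ± 0.18, -2.65) fell too. In all, 222 genes were higher and 217 lower (limma, Benjamini-Hochberg). With the block 876 and 756 were, and the first set alone gave 2063. All 439 were also called with the block.

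Other genes that rose were Cybb (3.45 ± 0.19, and 3.64 with the block), Lilr4b (3.44 ± 0.30, 3.20), Lilrb4a (3.35 ± 0.25, 3.06), Naip5 (3.26 ± 0.26, 3.50), Cst7 (3.17 ± 0.17, 3.04), Sccpdh (3.08 ± 0.21, 3.08), the inflammatory caspases Casp4 (2.69 ± 0.20, 2.44) and Casp1 (2.60 ± 0.43, 1.94), Ccl5 (1.91 ± 0.13, 1.85), the follicle homing receptor Cxcr5 (1.79 ± 0.27, 2.16), Ccr6 (1.76 ± 0.22, 1.57), the cytokine Ifng (1.67 ± 0.14, 1.69) and Klrg1 (1.51 ± 0.25, 1.27). Rasgrp2 (-2.83 ± 0.34, -2.32 with the block), Prkd3 (-2.39 ± 0.23, -2.12), Cd7 (-2.29 ± 0.36, -1.73), Sgk3 (-2.28 ± 0.21, -2.01), Rasa3 (-2.27 ± 0.41, -1.62), Gpr146 (-2.26 ± 0.30, -1.93) and Bcl2 (-1.33 ± 0.14, -1.43) fell. These genes had adjusted p from 3.36e-05 to 0.041 without the block (limma, Benjamini-Hochberg). The folds of Lilr4b and Sccpdh are lower bounds at best, since FR1 (4.82 and 4.87) lay below percentile 25 of its arrays.

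With the array set as a block, limma also called the chemokine receptor Ccr8 (3.23 ± 0.19, adjusted p = 3.43e-08, against 1.98 and 0.307 without), Pdcd1 (2.68 ± 0.13, 1.54e-08, against 2.02 and 0.0594), Cxcr3 (2.54 ± 0.14, 2.45e-08, against 1.92 and 0.0577), the costimulatory receptor Tnfrsf9 (2.52 ± 0.13, 2.17e-08, against 1.63 and 0.238) and the orphan nuclear receptor Nr4a2 (1.20 ± 0.14, 3.84e-05, against 0.14 and 0.93), all higher. The phosphatase Dusp4 turned direction, from -0.81 ± 1.11 (adjusted p = 0.732) without the block to 0.97 ± 0.14 (0.000221) with it. Cd4 likewise went from -0.34 ± 0.53 (0.766) to 0.50 ± 0.13 (0.028). Cd69 was at -1.22 ± 0.67 without and -0.17 ± 0.18 with the block, and Foxp3 at -0.56 ± 0.31 and -0.12 ± 0.15, none of which passed.

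Of the 20 naive and lymphoid homing genes, 12 fell over all genes and 19 adjusted over the list alone, and 17 and 20 with the block (median -1.76, camera adjusted p = 3.38e-24, adjusted p = 0.179 with an estimated correlation). With the block the median was -1.41 (6.33e-37). Of 32 effector Treg genes, 9 rose, and 19 rose and 1 fell adjusted over the list alone (median 1.26, camera adjusted p = 7.52e-11, adjusted p = 0.2 with an estimated correlation). With the block 24 rose and 1 fell (median 1.30, 1.83e-34). Of 13 co-inhibitory receptors, 4 rose, among them Pdcd1lg2 (1.72 ± 0.13, 1.78 with the block), Lag3 (1.68 ± 0.22, 1.95) and Cd200r1 (1.55 ± 0.18, 1.34), and 7 rose adjusted over the list alone (median 0.73, camera adjusted p = 0.000146, adjusted p = 0.179 with an estimated correlation). With the block 9 rose on both counts (median 0.61, 8.3e-10). Of 21 Treg identity genes, 3 rose, and 6 rose and 1 fell adjusted over the list alone (median 0.48, camera adjusted p = 0.00463, adjusted p = 0.761 with an estimated correlation). With the block 12 rose and 3 fell (median 0.59, 6.13e-11). Of 26 genes of NK receptors and cytotoxicity, 5 rose and 2 fell, and 10 and 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.00123, adjusted p = 0.179 with an estimated correlation). With the block the median was 0.25 (0.000224).

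Of 27 genes of the type I interferon response, 1 rose and 3 fell, and 3 and 8 adjusted over the list alone (median -0.19, camera adjusted p = 0.0206, adjusted p = 0.269 with an estimated correlation). With the array set as a block the median was -0.36 (0.000172). Among them Oas2 (-1.15 ± 0.19, -1.23 with the block) and Usp18 (-0.92 ± 0.17, -0.93) fell. Of 20 cholesterol synthesis genes, 1 fell, the isomerase Idi1 (-1.18 ± 0.23, -0.93 with the block), and 8 fell adjusted over the list alone (median -0.51, camera adjusted p = 5.47e-06, adjusted p = 0.2 with an estimated correlation). The median was -0.32 with the block (7.37e-06). The ribosomal protein genes were lower as a group (median -0.25, camera adjusted p = 2e-05, adjusted p = 0.188 with an estimated correlation). The median was -0.22 with the block (5.38e-06). The 28 chemokine receptors and integrins went both ways, with 2 up and 2 down, and 8 and 6 adjusted over the list alone (median 0.01, camera adjusted p = 0.921, and 0.12 and 0.0537 with the block). Of 30 T helper regulators and cytokines, 4 rose and 1 fell (median 0.19, camera adjusted p = 0.11). With the block 10 rose and 4 fell (median 0.16, 0.00421, adjusted p = 0.313 with an estimated correlation).

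Some list calls did not hold within a set. The TCR-induced immediate genes were lower without the block (median -0.67, camera adjusted p = 0.00143, adjusted p = 0.803 with an estimated correlation), and with it 7 of 32 rose and 3 fell (median 0.03, 0.0982). Glycolysis was lower without the block (median -0.30, camera adjusted p = 0.0326, adjusted p = 0.839 with an estimated correlation) and its direction turned with it (0.19, 0.391). The markers of macrophages and monocytes were higher without the block (median 0.27, camera adjusted p = 0.00556, adjusted p = 0.761 with an estimated correlation) and not with it (0.08, 0.21), where Cybb was the 1 marker of 21 that rose. Without FR1 replicate 1 or 2 the count of 439 fell to 54 and 57, and without FR2 replicate 1 or 2 to 247 in both cases. With the block it was 1007 without FR1 replicate 2, and 990 and 910 without FR3 Klrg1- replicates 1 and 2.

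**Figure D2:**
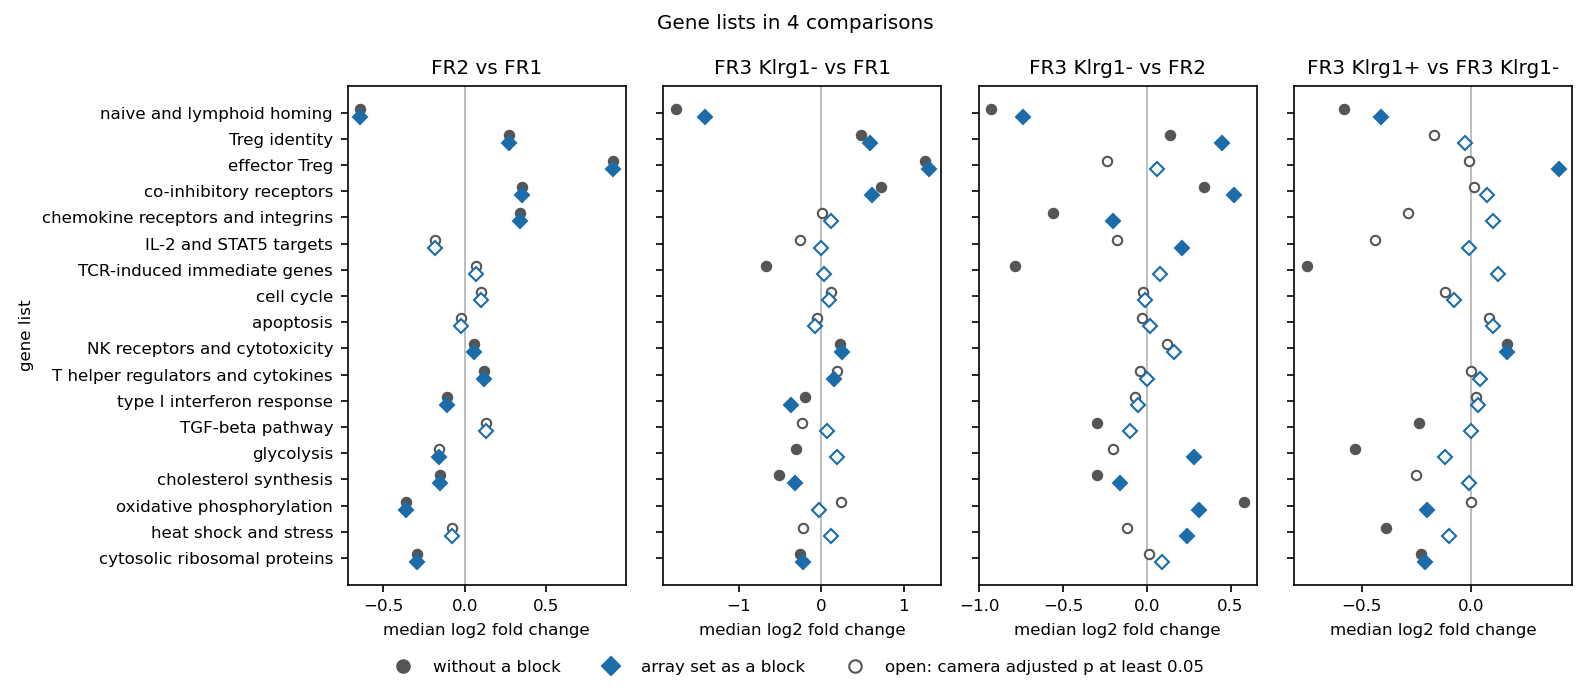
Median log2 fold change of 18 gene lists in 4 comparisons, without a block (circles) and with the array set as a block (diamonds), where open symbols have a camera adjusted p of at least 0.05. The naive and lymphoid homing list is lower in all 4, with medians of -0.64, -1.76, -0.93 and -0.58 without a block.

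The comparison of FR3 Klrg1- with FR2 isolates the CD69 gate, since both groups are CD62Llo and Klrg1-. CD69+ cells had more Penk, which rose by 3.60 ± 0.14 (n = 4 and 2; 3.53 with the array set as a block), Il1r2 (2.77 ± 0.25, 2.51), the surface protein Nrn1 (2.45 ± 0.25, 2.71) and Itgb8 (1.52 ± 0.15, 1.68). S1pr1 (-2.19 ± 0.10, -2.18 with the block), Ccr2 (-2.05 ± 0.23, -2.35), the integrin chain Itga2 (-1.65 ± 0.22, -1.93) and the homing receptor Gpr15 (-1.55 ± 0.14, -1.45) fell. In all, 27 genes were higher and 28 lower (limma, Benjamini-Hochberg). With the block 561 and 387 were, and the first set alone gave 1318. All 55 were also called with the block.

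Cst7 (2.23 ± 0.17, and 2.10 with the block), the gap junction gene Gjb2 (1.90 ± 0.24, 1.57), the guanylate cyclase subunit Gucy1a1 (1.82 ± 0.13, 1.69), Rida (1.70 ± 0.18, 1.64), the tetraspanin Cd81 (1.67 ± 0.12, 1.61), Cybb (1.56 ± 0.19, 1.75), Sccpdh (1.55 ± 0.21, 1.54), Pdcd1lg2 (1.26 ± 0.13, 1.32) and the transcription factor Batf (1.11 ± 0.14, 0.97) rose. Anxa1 (-1.82 ± 0.17, -1.80 with the block), Ripor2 (-1.71 ± 0.18, -1.47), Satb1 (-1.52 ± 0.21, -1.23), L1cam (-1.51 ± 0.12, -1.47), Rap1gap2 (-1.45 ± 0.11, -1.48), Dnah8 (-1.40 ± 0.18, -1.38) and Igfbp4 (-1.35 ± 0.18, -1.17) fell. The adjusted p of the named genes ran from 0.000108 to 0.0388 (limma, Benjamini-Hochberg).

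Other genes passed in limma with the block alone. Ccr8 rose by 2.66 ± 0.19 with it (adjusted p = 1.54e-06, against 1.41 and 0.514 without), Tnfrsf9 by 2.44 ± 0.13 (1.47e-07, against 1.55 and 0.352), Cd83 by 1.89 ± 0.13 (1.54e-06, against 0.93 and 0.552), Pdcd1 by 1.67 ± 0.13 (3.27e-06, against 1.01 and 0.413), Lag3 by 1.40 ± 0.15 (4.92e-05, against 1.13 and 0.105) and Tnfrsf4 by 1.35 ± 0.13 (1.57e-05, against 0.69 and 0.533). S100a4 fell by 1.90 ± 0.15 with it (3.27e-06, against -0.51 and 0.831) and the IL-18 receptor chain Il18r1 fell by 1.70 ± 0.14 (5.65e-06, against -0.97 and 0.463). Dusp4 and Nr4a2 turned direction, from -0.71 ± 1.11 (0.814) and -0.14 ± 0.67 (0.947) without the block to 1.07 ± 0.14 (0.000279) and 0.92 ± 0.14 (0.00128) with it. With the block Cd69 itself was at 0.07 ± 0.18, Klrg1 at 0.37 ± 0.19, Cd4 at 0.31 ± 0.13 and Foxp3 at -0.14 ± 0.15, none of which passed.

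Of the 20 naive and lymphoid homing genes, 3 fell, and 13 adjusted over the list alone (median -0.93, camera adjusted p = 9.64e-13, adjusted p = 0.179 with an estimated correlation). With the block 12 fell (median -0.74, 2.66e-18). Of 28 chemokine receptors and integrins, 3 fell, and 1 rose and 12 fell adjusted over the list alone (median -0.56, camera adjusted p = 5.52e-06, adjusted p = 0.2 with an estimated correlation). With the block 5 rose and 11 fell (median -0.20, 0.000349). Of 13 co-inhibitory receptors, 1 rose, and 5 adjusted over the list alone (median 0.34, camera adjusted p = 0.00219, adjusted p = 0.179 with an estimated correlation), and 7 rose with the block (median 0.52, 4.76e-08). Of 21 Treg identity genes, 2 rose, and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.0321, adjusted p = 0.803 with an estimated correlation). With the block 9 rose and 1 fell (median 0.45, 1.28e-11).

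The 36 oxidative phosphorylation genes were higher as a group (median 0.58, camera adjusted p = 2.85e-07, adjusted p = 0.216 with an estimated correlation). Adjusted over the list alone 4 rose, and with the block 5 rose over all genes and 12 over the list alone (median 0.31, 6.31e-10), with Uqcrb the largest (0.94 ± 0.15). The 32 effector Treg genes went both ways: 2 rose, and 2 rose and 4 fell adjusted over the list alone (median -0.24, mean 0.02, test lower, camera adjusted p = 0.518), and 10 rose and 7 fell with the block (median 0.06, 0.0891). Cholesterol synthesis was lower (median -0.30, camera adjusted p = 0.00305, adjusted p = 0.431 with an estimated correlation). With the block the median was -0.16 (0.0172).

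The block turned or ended several list calls. The TCR-induced immediate genes were lower without it (median -0.79, camera adjusted p = 0.00166, adjusted p = 0.803 with an estimated correlation), and with it 6 of 32 rose (median 0.08, 0.0676). IL-2 and STAT5 targets (median -0.18, adjusted p = 0.706 without the block) and glycolysis (-0.20, 0.288) were higher with it (0.21 and 0.00983, 0.28 and 0.00086, with adjusted p = 0.418 and 0.466 with an estimated correlation). Heat shock and stress genes (median -0.12, adjusted p = 0.876 without the block) and the T cell markers (-0.13, 0.694) were likewise higher with it, where 2 of 22 and 1 of 14 rose (0.24 and 0.00296, 0.13 and 0.0423, with adjusted p = 0.552 and 0.331 with an estimated correlation). The TGF-beta pathway was lower without it (median -0.30, 0.00463, and -0.10, 0.413 with it), and the markers of macrophages and monocytes (0.26, 0.00123, and 0.09, 0.218) and of NK cells (0.20, 0.0443, and 0.03, 0.512) were higher without it. For these 3 lists the adjusted p without the block was 0.761, 0.672 and 0.678 with an estimated correlation. Without FR1 replicate 1 or 2 limma called 9 genes in each case, without FR2 replicate 1 or 2 it called 2, and without FR3 Klrg1- replicates 1, 3 and 4 in turn 26, 25 and 17. With the block it called 302 and 521 without FR2 replicates 1 and 2, and 312 and 414 without FR3 Klrg1- replicates 1 and 2.

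The comparison of FR3 Klrg1+ with FR3 Klrg1- isolates the Klrg1 gate and rests on 1 FR3 Klrg1+ array, taken to vary like the other groups. Klrg1 rose by 5.21 ± 0.33 (n = 1 and 4; 4.96 with the array set as a block), the cytotoxic protease Gzmb by 2.00 ± 0.22 (1.85), Pparg, the nuclear receptor known from Tregs of fat tissue, by 2.14 ± 0.20 (2.09) and the hypoxia-inducible factor Epas1 by 1.80 ± 0.21 (1.99). Cxcr5 fell by 3.32 ± 0.34 (-2.95 with the block). The subunits of soluble guanylate cyclase, Gucy1b1 (-1.83 ± 0.22, -1.62) and Gucy1a1 (-1.65 ± 0.17, -1.78), and the cytokine receptor chain Il6st (-1.46 ± 0.15, -1.37) fell too. In all, 14 genes were higher and 8 lower (limma, Benjamini-Hochberg). With the block 426 and 563 were. The second set alone gave 744, on 1 residual degree of freedom and nearly the same pooled variance for every gene, so that count adds no support. All 22 were also called with the block.

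Nckap5 (2.23 ± 0.23, and 2.16 with the block), Pcyt1a (2.22 ± 0.22, 2.07), Ppfibp2 (2.13 ± 0.25, 1.98), the steroid synthesis enzyme Cyp11a1 (1.79 ± 0.14, 1.82), the chemokine receptor Ccr1 (1.77 ± 0.15, 1.82) and the protease Ctsh (1.74 ± 0.15, 1.72) also rose, though the other probe set of Nckap5 gave 0.60. Mboat1 (-2.19 ± 0.17, -2.27 with the block), Atp1b1 (-2.07 ± 0.23, -1.99) and Pdlim1 (-1.60 ± 0.18, -1.66) fell. Cyp11a1 (4.73), Ccr1 (3.43) and Ctsh (4.99) in FR3 Klrg1-, and Mboat1 (5.01) and Gucy1b1 (4.86) in FR3 Klrg1+, lay below percentile 25 of the arrays, so their folds are lower bounds at best. The adjusted p of the named genes ran from 0.00548 to 0.0333 (limma, Benjamini-Hochberg).

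With the block limma also called the RNA gene Flicr, a neighbour of Foxp3, which fell by 3.47 ± 0.18 (adjusted p = 8.56e-08, against -2.71 and 0.216 without). Ccr7 fell by 2.42 ± 0.16 (1.27e-06, against -3.02 and 0.104), Actn1 fell by 2.18 ± 0.15 (1.77e-06, against -2.62 and 0.0756), Gpr83 fell by 1.90 ± 0.22 (0.000182, against -2.27 and 0.107), Id3 fell by 1.45 ± 0.20 (0.00103, against -1.25 and 0.185) and the TGF-beta anchor Lrrc32 fell by 0.98 ± 0.16 (0.00326, against -2.36 and 0.512). Tmem273 rose by 2.23 ± 0.18 (6.09e-06, against 2.77 and 0.105), Lilr4b by 2.21 ± 0.29 (0.000537, against 2.46 and 0.0949), Cxcr6 by 1.97 ± 0.27 (0.0008, against 2.60 and 0.2), Fgl2 by 1.69 ± 0.23 (0.000821, against 1.45 and 0.196), the transcription factor Gata3 by 1.33 ± 0.16 (0.000346, against 0.71 and 0.66), Il10 by 1.26 ± 0.25 (0.011, against 0.70 and 0.673), the co-inhibitory receptor Havcr2 by 1.19 ± 0.15 (0.000477, against 1.40 and 0.0896) and Pdcd1 by 1.03 ± 0.16 (0.00229, against 0.37 without, which did not pass). Cd160, like Havcr2 and Pdcd1 a co-inhibitory receptor, fell by 1.06 ± 0.16 (0.00173, against -0.54 and 0.694), and of the 13 in that list 4 rose and 1 fell with the block (median 0.07, camera adjusted p = 0.178, and 0.01, 0.602 without). Cd69 (-0.13 ± 0.21), Cd4 (0.16 ± 0.16) and Foxp3 (-0.15 ± 0.18) did not pass with the block.

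Of the 20 naive and lymphoid homing genes, 1 fell, and 7 adjusted over the list alone (median -0.58, camera adjusted p = 8.32e-07, adjusted p = 0.267 with an estimated correlation). With the block 2 rose and 6 fell (median -0.41, 6.32e-06). Of 26 genes of NK receptors and cytotoxicity, Klrg1 and Gzmb rose, and 6 rose and 2 fell adjusted over the list alone (median 0.16, camera adjusted p = 0.0154, adjusted p = 0.2 with an estimated correlation). With the block 6 rose and 2 fell (median 0.16, 0.00276). Klrg1 is a member of this list and was separated by the sort itself, and the list was not tested without it. The ribosomal protein genes were lower as a group (median -0.23, camera adjusted p = 0.00166, adjusted p = 0.266 with an estimated correlation). The median was -0.21 with the block (0.000568). Of 32 effector Treg genes, 1 rose, and 3 rose and 1 fell adjusted over the list alone (median -0.01, mean 0.20, test higher, camera adjusted p = 0.172). With the block 9 rose and 1 fell (median 0.40, camera adjusted p = 4.76e-08, adjusted p = 0.396 with an estimated correlation).

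The markers of macrophages and monocytes were lower as a group in camera, with a median of -0.31, and of -0.51 with the block. Neither call held with an estimated correlation. FR3 Klrg1- replicates 3 and 4 had the highest mean of these markers of all arrays (6.13 and 6.23). It was 5.76 on FR3 Klrg1+, 5.77 on the array placed in no group, and 5.80 and 5.91 on FR3 Klrg1- replicates 1 and 2. The difference thus lay in high values on the reference arrays of the second set. Besides the effector Treg genes, lists called with the block alone were oxidative phosphorylation, lower (median -0.20, camera adjusted p = 5.52e-05, adjusted p = 0.541 with an estimated correlation, and 0.00, 0.225 without the block), and the plasma cell markers, higher (0.42, 0.0109, adjusted p = 0.437 with an estimated correlation, and 0.30, 0.0955 without). Of 36 oxidative phosphorylation genes 1 fell with the block over all genes and 10 over the list alone, and of 5 plasma cell markers 0 passed in limma over all genes and 3 rose over the list alone. Lists that were lower without the block and did not pass with it were glycolysis (median -0.53, 0.000292, and -0.12, 0.146), the TGF-beta pathway (-0.24, 0.0244, and 0.00, 0.883), heat shock and stress (-0.39, 0.0191, and -0.10, 0.538) and the TCR-induced immediate genes, whose direction turned (-0.75, 0.00222, and 0.12, 0.179). Their adjusted p with an estimated correlation, without the block, was 0.761, 0.803, 0.761 and 0.803. Without FR1 replicate 1 or 2 limma called 3 genes in each case, without FR2 replicate 1 or 2 it called 1, and without FR3 Klrg1- replicate 2 it called 12. With the block it called 1553 without FR3 Klrg1- replicate 4.

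**Figure D3:**
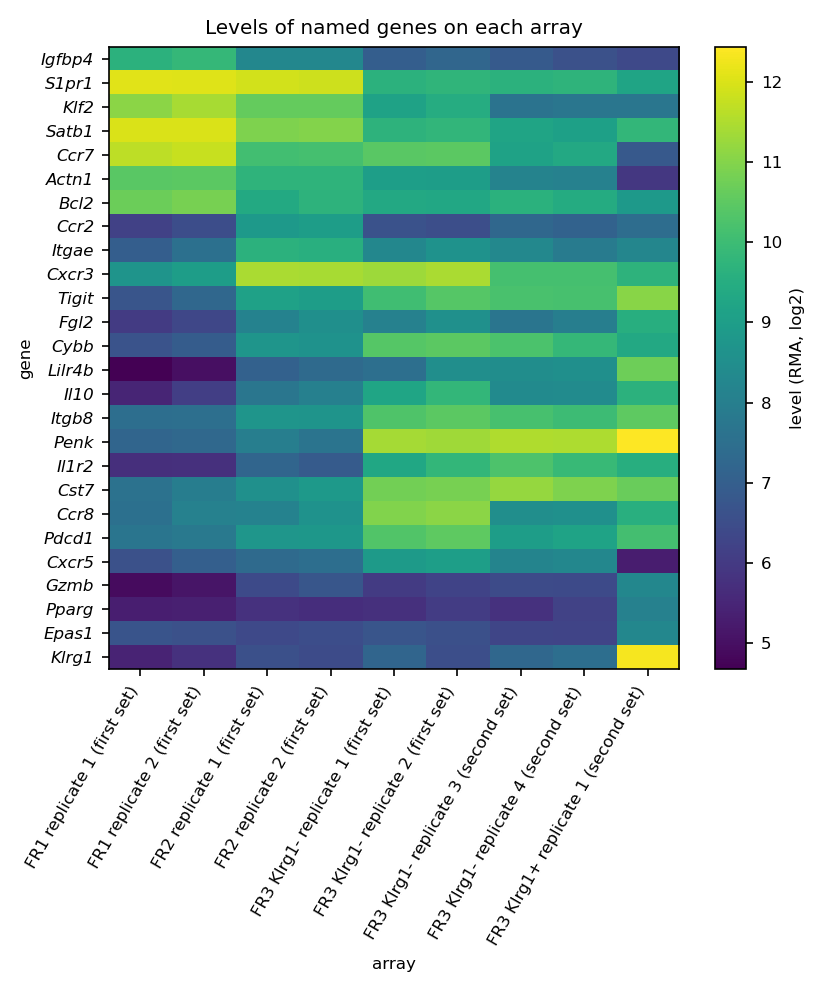
Level of 26 named genes (RMA, log2) on each of the 9 grouped arrays, 1 column per array and 1 line per gene, with the array set in the column label. Klrg1 is at 12.33 on the FR3 Klrg1+ array, and Penk rises by 3.60 from FR2 to FR3 Klrg1-.

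The comparison of FR3 Klrg1+ with FR1 spans all 3 gates. No array set holds both groups, so the value with the block runs through the FR3 Klrg1- arrays of each set, and no value within a set exists. Klrg1 rose by 6.73 ± 0.36 (n = 1 and 2, and 6.23 with the array set as a block). The receptor genes Lilr4b and Lilrb4a rose by 5.90 ± 0.42 (5.41) and 5.29 ± 0.35 (4.70), Penk by 5.19 ± 0.19 (5.06) and the chemokine receptor Cxcr6 by 4.84 ± 0.64 (3.59). Ccr7 (-4.89 ± 0.55, -3.68 with the block), the cytoskeletal gene Actn1 (-4.52 ± 0.41, -3.64) and Gpr83 (-3.72 ± 0.42, -2.97) fell. In all, 297 genes were higher and 330 lower (limma, Benjamini-Hochberg), and 741 and 843 with the block, which called 623 of the 627.

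Tigit (4.08 ± 0.24, and 4.12 with the block), Il10 (3.87 ± 0.59, 5.01), Il1r2 (3.83 ± 0.35, 3.29), Cysltr2 (3.64 ± 0.57, 2.43), Alcam (3.46 ± 0.49, 2.42), Fgl2 (3.36 ± 0.35, 3.85), Gzmb (3.28 ± 0.24, 2.97), Casp4 (3.04 ± 0.28, 2.54), Itgb8 (3.03 ± 0.21, 3.33), Cd200r1 (2.72 ± 0.26, 2.31), Ccl5 (2.54 ± 0.18, 2.43) and Havcr2 (2.13 ± 0.24, 1.71) rose. St8sia1 (-3.71 ± 0.46, -2.74 with the block), Klf2 (-3.53 ± 0.75, -1.89), Atp1b1 (-3.51 ± 0.26, -3.35), the kinase Txk (-3.42 ± 0.18, -3.40), Igfbp4 (-3.36 ± 0.25, -3.00), Sgk3 (-3.24 ± 0.30, -2.71), S1pr1 (-2.87 ± 0.15, -2.86) and Bcl2 (-1.91 ± 0.20, -2.12) fell. Their adjusted p ran from 9.22e-05 to 0.0493 (limma, Benjamini-Hochberg). As Lilr4b (4.82) and Cysltr2 (4.77) in FR1 and Sgk3 (5.06) in FR3 Klrg1+ lay below percentile 25 of the arrays, their folds are lower bounds at best. With the block limma also called Ccr8 (4.26 ± 0.29, adjusted p = 6.29e-07, against 1.77 and 0.349 without) and Pdcd1 (3.71 ± 0.21, 8.45e-08, against 2.39 and 0.0774), both higher, and Flicr, which fell by 4.39 ± 0.23 (6.2e-08, against -2.85 and 0.0725). Cd69 (-2.40 ± 0.95, and -0.30 ± 0.28 with the block), Cd4 (-1.02 ± 0.75, 0.66 ± 0.21) and Foxp3 (-1.15 ± 0.44, -0.26 ± 0.24) did not pass.

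Of the 20 naive and lymphoid homing genes, 15 fell, and 17 adjusted over the list alone (median -2.46, camera adjusted p = 3.88e-19, adjusted p = 0.179 with an estimated correlation), and 18 fell with the block (median -1.86, 1.21e-30). Of 32 effector Treg genes, 9 rose and 1 fell, and 15 and 2 adjusted over the list alone (median 1.01, camera adjusted p = 2.79e-06, adjusted p = 0.269 with an estimated correlation), and 26 rose and 1 fell with the block (median 1.84, 9.02e-32). Of 13 co-inhibitory receptors, 5 rose, and 6 rose and 2 fell adjusted over the list alone (median 0.70, camera adjusted p = 0.0108, adjusted p = 0.2 with an estimated correlation). The median was 0.63 with the block (4.34e-06). Of 26 genes of NK receptors and cytotoxicity, 7 rose and 1 fell, and 9 and 1 adjusted over the list alone (median 0.34, camera adjusted p = 0.00166, adjusted p = 0.179 with an estimated correlation). The median was 0.32 with the block (1.15e-05). This list too holds Klrg1, which the sort separated, and it was not tested without that gene. Of 32 ribosomal protein genes, 2 fell, and 11 adjusted over the list alone (median -0.47, camera adjusted p = 7.46e-06, adjusted p = 0.179 with an estimated correlation). With the block the median was -0.45 (5.46e-08). Cholesterol synthesis was lower too (median -0.55, 0.000325, adjusted p = 0.269 with an estimated correlation). With the block the median was -0.21 (0.00213).

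The TCR-induced immediate genes turned from lower (median -1.40, camera adjusted p = 6.51e-05, adjusted p = 0.803 with an estimated correlation) to higher with the block, where 7 of 32 rose and 1 fell (0.28, 0.0221, adjusted p = 0.731 with an estimated correlation). IL-2 and STAT5 targets (median -0.70, 0.0316, and 0.07, 0.428 with the block), the TGF-beta pathway (-0.44, 0.0382, and 0.10, 0.873) and glycolysis (-0.84, 0.00013, and 0.01, 0.855) were lower without the block alone, and their adjusted p was 0.761, 0.803 and 0.761 with an estimated correlation. Lists called with the block alone were Treg identity (median 0.87, camera adjusted p = 4.11e-07, with 11 higher and 3 lower), T helper regulators and cytokines (0.20, 0.0237, 10 and 4) and chemokine receptors and integrins (0.54, 0.0201, 11 and 5), all higher, and oxidative phosphorylation (-0.25, 0.000786, 0 and 3 by limma) and the type I interferon response (-0.28, 0.0283, 1 and 6), both lower. With an estimated correlation these had adjusted p = 0.237, 0.396, 0.468, 0.64 and 0.464, and without the block camera gave 0.325, 0.586, 0.908, 0.667 and 0.292. Without FR1 replicate 1 or 2 limma called 91 and 102 genes, and without FR2 replicate 1 or 2 it called 267 in both cases. With the block it called 1031 without FR1 replicate 2, and 1049 and 917 without FR3 Klrg1- replicates 1 and 2.

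Across all comparisons 50 of the 145 list tests passed in camera with the preset correlation, and 50 with the array set as a block. With an estimated correlation 0 held without the block (fry called 31), and 4 held with it: the naive and lymphoid homing list in FR2 against FR1 (adjusted p = 0.0406), FR3 Klrg1- against FR1 (0.0264), FR3 Klrg1- against FR2 (0.0406) and FR3 Klrg1+ against FR1 (0.0264).

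The step from FR1 to FR2 and the step from FR3 Klrg1- to FR3 Klrg1+ share no arrays and were compared across genes. They share the estimate of each gene's spread, so their calls are not independent, while the numbers by chance below take them as independent. The step to FR3 Klrg1+ rests on 1 array of that group. Their fold changes correlated at 0.181 over 19938 genes (Pearson, Spearman 0.151), and at 0.213 with the array set as a block, where genes are not independent replicates. Without the block 1 gene was higher at both steps and 1 lower, where 0.0288 and 0.00441 would overlap by chance. With the block, added after the sets were seen, 52 genes were higher at both steps, where 8.35 would overlap by chance, and 78 were lower at both, where 13.0 would. In opposite directions, 13 were higher and then lower, which is 1.18 times the number by chance, and 6 were lower and then higher, 0.612 times that number. Genes higher at both steps included Gzmb (1.56 ± 0.15 and 1.85 ± 0.18), Fgl2 (2.16 ± 0.19 and 1.69 ± 0.23), Il10 (2.10 ± 0.21 and 1.26 ± 0.25), Lilr4b (2.39 ± 0.23 and 2.21 ± 0.29) and Cxcr6 (1.64 ± 0.22 and 1.97 ± 0.27). Genes lower at both included Ccr7 (-1.61 ± 0.13 and -2.42 ± 0.16), Gpr83 (-1.52 ± 0.18 and -1.90 ± 0.22), Atp1b1 (-1.48 ± 0.17 and -1.99 ± 0.21) and Bcl2 (-1.23 ± 0.14 and -0.69 ± 0.17). These examples were chosen after their values were seen.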

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

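The tests in this part were chosen after the result was seen, except those on probe sets without a gene name, on called genes as bright as Cd69 and on quantile normalization.

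Of the 89 named genes checked in FR3 Klrg1-, the only group with 4 arrays, 2 had an array far from the others by Dixon's ratio at its critical value for 4 samples, where chance alone gives about 1 in 20 in a uniform group, here 4.45 genes. The test ignores the array sets, and the 2 arrays from each can hide a single far one. Lilr4b was at 7.52 on FR3 Klrg1- replicate 1, against a mean of 8.51 on the other 3 arrays. Ppfibp2 was at 6.66 on FR3 Klrg1- replicate 4, against a mean of 6.17. The array placed in no group had Klrg1 at 12.41, while its marker text says Klrg1- and FR1 stood at 5.61.

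The arrays split into 2 sets that did not follow the groups. That FR3 Klrg1- replicates 3 and 4 were FR3 Klrg1+ arrays under a wrong label is argued against by their Klrg1 (7.27 and 7.47), far below FR3 Klrg1+ (12.33). They correlated with the first-set arrays, which hold FR1, FR2 and FR3 Klrg1-, at 0.921 at most, against 0.981 at least between those arrays. The sets were formed from these same correlations, so this restates the split and is no separate test of the labels. At genes called in the first set, the mean of replicates 3 and 4 lay nearer FR3 Klrg1- than FR1 at 69.9% of 2063 and than FR2 at 65.1% of 1318. These shares were taken without removing the difference between the sets, and the labels themselves stay unproven. A scaling that keeps the order of values on each array is argued against by rank correlations, which it leaves as they are and which were 0.922 at most between the sets and 0.964 at least within a set, while quantile normalization moved neither correlation and decides nothing. Between the sets, 25.4% of probe sets without a gene name and 10.3% of named genes differed by at least 1 in FR3 Klrg1-, so a difference between array batches stays open, and it cannot be told apart from a difference between mice or sorts because the labels give no dates. No biological explanation was tested.

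The high Klrg1 on the array placed in no group, whose label was not changed, may come from a wrong marker text. At 2062 genes that differed between FR3 Klrg1- and FR1 in the first set, Klrg1 left out, it lay nearer FR3 Klrg1- of its own set than FR1 moved by the set difference in FR3 Klrg1- at 86.2%. An artefact of the Klrg1 probe set is argued against: at genes that differed by at least 1 between FR3 Klrg1+ and 1 FR3 Klrg1- array of the set, dim genes left out, the array differed from the other FR3 Klrg1- array in the same direction at 83.7% of 227 and 91.8% of 158, where no change would favour neither direction. That test followed 3 others: the array lay nearer FR3 Klrg1+ at 50.7% of the 988 genes called with the array set as a block, which decided nothing, and at 81% of the 21 called without it, and it shared the direction at 84.5% and 86.5% of the 988, which were chosen with both reference arrays and so favour a shared direction. NK cells in the sample are argued against by their markers, whose mean was -0.32 relative to the highest FR3 Klrg1- array of the set.

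The Cd69 transcript was no higher in the CD69+ sorts than in FR2. A failed gate is argued against by the 948 genes that limma called between FR3 Klrg1- and FR2 with the block. A saturated probe set stays open. In the first set the highest FR1 or FR2 array was above the highest FR3 Klrg1- array by 0.26, within 2 SD (SD 0.19 within groups). Of genes as bright, 73.6% had an SD over the first set no larger than that of Cd69. Saturation at that level would flatten these genes too, so this decides nothing. The brightest probe set reached at least 14.8 on every first-set array, so the arrays as a whole were not at a ceiling at the Cd69 level. A limit of the Cd69 probe set itself is not addressed by this. The planned test, 7 called genes among the 109 at least as bright in FR2 (3 higher), compares other probe sets and decides nothing. A candidate explanation is that handling before lysis induced Cd69 with other immediate genes in every gate of the first set. There the TCR-induced immediate genes were higher by a median of 1.87 in FR3 Klrg1-, 22 of 32 by at least 1. Cd69 is itself among the 32, and Egr1, another member, was higher by only 0.58. Heat shock and stress genes were higher by a median of 0.69. Handling stays open, since the labels give no handling times and the set is confounded with it. So does control of CD69 protein after transcription, which was not tested.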

How the results depend on the processing

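The alternatives with the array set as a block, within each array set, and without 1 array in the fit with the block were chosen after seeing the data; the others were fixed before. Without each array in turn the genes changed numbered 0 to 39 for FR2 against FR1, 54 to 448 for FR3 Klrg1- against FR1, 2 to 54 for FR3 Klrg1- against FR2, 1 to 28 for FR3 Klrg1+ against FR3 Klrg1- and 91 to 923 for FR3 Klrg1+ against FR1, and with the block 253 to 1331, 910 to 2063, 302 to 1318, 721 to 1553 and 917 to 2101. Where this left a group with 1 array, that array was assumed to vary like the others. List tests past the threshold numbered 47 to 51. Signal over background limits the dim genes: leaving out genes under the percentile 40 of the mean gave 49, 453, 52, 15 and 539 genes in the 5 comparisons.

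In the same order of comparisons, the array set as a block gave 850, 1632, 948, 989 and 1584 genes. The first set alone gave 1331, 2063 and 1318 for the comparisons it holds, and the second 744 for FR3 Klrg1+ against FR3 Klrg1-, a fit with 1 residual degree of freedom in which nearly every gene takes the same pooled variance (prior degrees of freedom 3822). Array weights gave 415, 1281, 730, 5089 and 6440, with weights of 0.187 and 0.206 for FR3 Klrg1- replicates 3 and 4. Only the 2 groups compared gave 1062, 247, 9, 0 and 7665, and in the last of these the groups coincide with the sets. The count of 0 was by limma, with 1231 genes at an unadjusted p under 0.05. Every row of the table gave 0 for FR2 against FR1 (limma, 1705 at an unadjusted p under 0.05) and 14 for FR3 Klrg1- against FR2. Quantile normalization gave 85 for FR3 Klrg1- against FR2 and 35 for FR3 Klrg1+ against FR3 Klrg1-, and the fold threshold gave 290 for FR3 Klrg1- against FR1. Of 145 list tests, 0 passed with an estimated correlation, 4 with it and the block, and 31 by fry. The first set alone gave 32 of 87 tests and the second 8 of 29, where fewer tests were run. The correlation of the steps was 0.181, and 0.213 with the array set as a block and 0.179 without the dim genes, the only alternatives run for it. Except for the block and the sets, the cause was not tested.

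The replicate number as a block gave 1669, 2355, 1586, 7859 and 8541 genes. Whether the numbers pair the arrays stays open. Deviations of replicate 1 from the group mean correlated across genes at 0.181, 0.144 and 0.023 between groups, with no reference for unpaired arrays. For the comparisons that the first set holds, this block called more genes than that set alone (1331, 2063 and 1318). By this block the FR3 Klrg1+ array, replicate 1 of the second set, is compared with replicates 1 of the first, which adds the difference between the sets.

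Turns of direction are given where a call passed on at least 1 side. Named genes of this kind, with the replicate block, the set block and the first set alone, were Dusp4 (0.97 against FR1 and 1.07 against FR2), Cd4 (0.50 against FR1) and Nr4a2 (0.92 against FR2), all in FR3 Klrg1-. Lists of this kind are given by adjusted p. With the replicate block these were the TCR-induced immediate genes in FR3 Klrg1- against FR1 (0.167) and FR2 (0.0867), glycolysis (0.424 and 0.00107) and IL-2 and STAT5 targets (0.014) and heat shock and stress (0.000934) against FR2. With the set block they were the TCR-induced immediate genes in FR3 Klrg1- against FR1 (0.0982) and FR2 (0.0676), FR3 Klrg1+ against FR3 Klrg1- (0.179) and against FR1 (0.0221). With it an estimated correlation gave 0.77, 0.766, 0.785 and 0.731, and fry 0.176, 0.179, 0.552 and 0.176. Glycolysis turned with the set block against FR1 (0.391, 0.785 with an estimated correlation, 0.314 by fry) and FR2 (0.00086). IL-2 and STAT5 targets turned in FR3 Klrg1- against FR2 (0.00983, 0.0464 by fry) and in FR3 Klrg1+ against FR1 (0.428, 0.766, 0.145), and the TGF-beta pathway in the latter (0.873, 0.98, 0.388). Heat shock and stress (0.00296) and the T cell markers (0.0423, 0.00879 by fry) turned in FR3 Klrg1- against FR2, and chemokine receptors and integrins in FR3 Klrg1+ against FR1 (0.0201). In the first set alone the values were 0.119 and 0.058 for the TCR-induced immediate genes, 0.383 and 0.000867 for glycolysis, 0.0107 for IL-2 and STAT5 targets, 0.0025 for heat shock and stress and 0.0499 for the T cell markers, and in the second 0.282 for the TCR-induced immediate genes. In the other alternatives of the named genes 2312 stayed on their side of the threshold, among them values that changed sign and passed on neither side (Cd4 in FR3 Klrg1- against FR2 went from -0.53 to 0.31 with the set block, and Cd69 from -0.98 to 0.07), 462 no longer passed and 181 passed anew, and for lists these were 988, 179 and 36.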

Other observations

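This part reports values chosen after the data were seen. With the array set as a block, 52 genes were higher both from FR1 to FR2 and from FR3 Klrg1- to FR3 Klrg1+. At the step between, from FR2 to FR3 Klrg1-, most of these did not pass, among them Fgl2 (-0.01) and Cxcr6 (-0.02). There 9 were higher again, among them Il10 (1.64), Tigit (1.18), Pdcd1 (1.67), Lilrb4a (1.23), the cytokine subunit Ebi3 (1.10) and Penk (3.53). Another 10 were lower at that step: Il18r1 (-1.70), Anxa1 (-1.80), Gpr15 (-1.45), Itga2 (-1.93), the eosinophil and T cell chemokine receptor Ccr3 (-0.96), Cpm (-1.58), Gna15 (-1.08), Klrb1f (-0.64), Axin2 (-0.99) and Hlf (-0.50). The middle step shares the FR2 arrays with the first, so a high value in FR2 enters the first step as a rise and the middle step as a fall.

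Of the 78 genes lower at both outer steps, 9 were also lower at the middle one, among them Actn1 (-0.72), Txk (-1.39), Pdlim1 (-0.93), Treml2 (-0.76) and Sgk3 (-0.80). Another 14 were higher there, among them the cytokine Mif (0.95), Tnfsf8 (1.58), the CD30 ligand, and the glutathione transferase Gsta4 (1.60). The rest did not pass at the middle step.

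The array placed in no group had Klrg1 at 12.41, Cd69 at 9.86, Cd4 at 10.21 and Foxp3 at 9.85 (RMA, log2). Its Ccr7 was at 6.72, Actn1 at 5.90, Igfbp4 at 6.41, S1pr1 at 9.23 and Klf2 at 7.58. Penk was at 12.46, Il1r2 at 9.95, Gzmb at 8.76, Pparg at 8.26, Epas1 at 7.41, Cxcr5 at 5.66, Lilr4b at 10.53, Tigit at 11.02 and Il10 at 9.90. On the FR3 Klrg1+ array Ccr7 was at 6.84, Actn1 at 5.94, Gzmb at 8.28, Pparg at 8.08, Epas1 at 8.27 and Cxcr5 at 5.28. In FR3 Klrg1- of the same set the means were 9.26, 8.12, 6.43, 5.99, 6.28 and 8.24 (n = 2).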
